A study of Homo sapiens with 6 samples.

How the data were processed

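Total RNA of ARPE-19 cells was sequenced after 24 h with 320 nM cinobufagin or DMSO, with 3 libraries in each group, per the labels. The deposited values are FPKM (fragments scaled to transcript length and to the mapped total of the library) per gene, per the file headers, and were given to 2 decimals. The submitters' processing notes name Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 and the genome build GRCh38.p13, without saying which step each served. The selection of RNA, the strand setting and the read totals are not given in the sources used here. FPKM divides by transcript length and by the mapped total of each library, so a change in a few abundant genes shifts the values of all others, and counting error cannot be taken from it.

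The deposited table names its control columns mock, and each was taken as the DMSO library of the same number, since the series has only these 2 groups. Entries without a gene ID, 19 in all, held displaced annotation text and were left out, which left 17945 genes. Entrez gene IDs were matched to symbols with a RefSeq gene table of assembly GRCh38.p14, used for names only. A symbol was found for 17881 genes, 64 had none, and 17816 were protein-coding. Mitochondrially encoded genes were not analysed here. Positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, with a transcript length for 17706 genes. Low values were checked for whole-read steps. In 1624 genes, ratios near 2, 3 and 4 times the smallest value were seen 408, 151 and 74 times, against 280.5, 111 and 50 times in windows of the same width beside them. Reads were not recovered from these steps, since RSEM assigns fractions of reads and the values are rounded, so no count model was used. No pair of libraries held identical values (0 pairs).

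Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept, which gave 11599 genes. The log2 of FPKM with a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with the mean-variance trend (limma-trend), as cinobufagin minus DMSO over the 6 libraries without a block. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. SE is the moderated standard error of the log2 fold change, and SD is over the 3 libraries of a group in FPKM. Gene lists, 33 in number, were tested with camera from limma at a preset correlation of 0.01 where at least 5 members were tested, and adjusted by Benjamini-Hochberg over the 27 lists. Of the 11 tested genes of the histone list, 10 are replication-dependent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

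The named genes followed a rule. It took the 12 largest rises and 12 largest falls in log2 fold change among genes past the threshold whose groups did not overlap, whose mean in the higher group was at or above the median over genes tested (13.4 FPKM) and which had a proper symbol. It added up to 4 members of each list with the largest change among those past the threshold, every tested sodium pump gene, and members that did not pass where a list was described. Some genes that the rule takes are not reported here. Of the 129 genes so taken, 35 overlap another listed gene in GENCODE 29, where unstranded reads cannot be told apart. The design, lists, rule and alternatives were fixed before the data were examined, except the removal of the length and GC trend, which was added after.

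The pipeline was tested on simulated data built for this comparison over 11526 genes with 200 changed genes. It recovered 90% of changes of 0.5 and 99% of changes of 1 on the log2 scale, with 6 false calls. The simulated list with moved members was called, and 0 of 30 others were. Noise was drawn separately for each gene, so false calls of lists with correlated members were not tested. The 200 genes moved up and down in equal number, and values were not rescaled to a library total. False calls under a change as broad as the 7849 genes called in the real data were therefore not tested. In the real data the estimated correlation reached 0.63, in the ribosomal protein list. The alternatives were limma without the trend, quantile normalization, median centring, no filter, a filter of at least 5 FPKM, a pseudocount of 0.1, a minimum log2 fold change of 1, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry, which tests whether a list moves one way without comparing it with other genes.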

Results

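RNA sequencing measured gene expression in ARPE-19 cells, a human retinal pigment epithelial cell line, after 24 h with 320 nM cinobufagin or with DMSO, the control treatment. Cinobufagin is a bufadienolide, a steroid of toad venom that inhibits Na+/K+-ATPase, the sodium pump of the plasma membrane. Each group held 3 libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. FPKM values were read for 17945 genes in each library. Their sums ranged from 538039 to 560721 in the DMSO libraries and from 534694 to 545499 in the cinobufagin libraries, and 14701 to 14896 genes had a value above 0. Read totals are not given in the sources used here. Steps between the low values were 0.98 to 1.03 times those of DMSO replicate 1. They do not show relative depth, since equal rounded values count toward every scale in that range (within 3%). The 10 most abundant genes took 9.34% to 9.62% of the summed FPKM in DMSO and 9.98% to 10.1% in cinobufagin libraries. Across the 11599 genes tested, which are not independent replicates, Pearson's r was 0.996 to 0.997 within groups and 0.962 to 0.963 between groups. The first principal component held 89.3% of the variance and separated the groups.

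The design asks how the transcriptome of ARPE-19 cells differs between cinobufagin and DMSO. Cinobufagin-treated cells had much lower transcript levels of mitotic, DNA replication and amino acid stress response genes, of several keratins and of inflammatory cytokines. In the autophagy and lysosome, NRF2 antioxidant, hypoxia and glycolysis, and histone lists more members rose than fell. These 4 lists and the mitosis list were called at a preset correlation between genes but not with an estimated one (camera). Of 11599 genes tested, 4552 rose, 3297 fell and 3750 did not pass (limma-trend, adjusted p under 0.05). Most changes were small, with a median size of 0.37 on the log2 scale among the genes called and a median SE of 0.06. Changes of at least 1 on the log2 scale were seen in 498 genes, of which 111 rose and 387 fell. The 3 values of one group lay wholly above those of the other in 70.8% of the genes tested, where chance gives 10%. Fold changes are of FPKM + 1, which understates the change of genes with low values.

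By the naming rule, with its floor of 13.4 FPKM in the higher group, the largest fall was that of KRT33B (gene ID 3884). This hair-type keratin gene lies at chromosome 17, 41363494 to 41369800 on GRCh38. Its level went from 178 ± 15.0 FPKM in DMSO to 0.577 ± 0.0115 in cinobufagin libraries (SD, n = 3 each), a log2 fold change of -6.82 (SE 0.06, limma adjusted p = 1.27e-14). KRT13 (gene ID 3860, chromosome 17, 41500981 to 41505705), another keratin gene, went from 36.6 ± 4.33 to 0.300 ± 0.141 FPKM, a log2 fold change of -4.85 (SE 0.10, limma adjusted p = 1.77e-11). DIO2 (gene ID 1734, chromosome 14, 80197527 to 80387757), which encodes the deiodinase that activates thyroid hormone, was 11.7-fold lower, at 245 ± 11.4 and 20.97 ± 0.771 FPKM (log2 fold change -3.48, SE 0.05, limma adjusted p = 4.82e-13). PTX3, a secreted pentraxin of innate immunity, fell by 2.79 on the log2 scale, and DKK1, a secreted Wnt inhibitor, fell by 2.74. S100A3 fell by 2.94 and S100A4 fell by 2.53 on the log2 scale. These neighbouring calcium-binding protein genes overlap on the same strand, so their reads are hard to separate. The folate receptor family gene FOLR3 fell by 2.67 on the log2 scale, the enamel-epithelium gene AMTN fell by 2.61 and the calmodulin-binding protein gene PCP4 fell by 2.59. The remaining pair among the 12 largest falls by this rule, PSAT1 and CHAC1, belongs to the stress response list described further on.

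**Figure D1:**
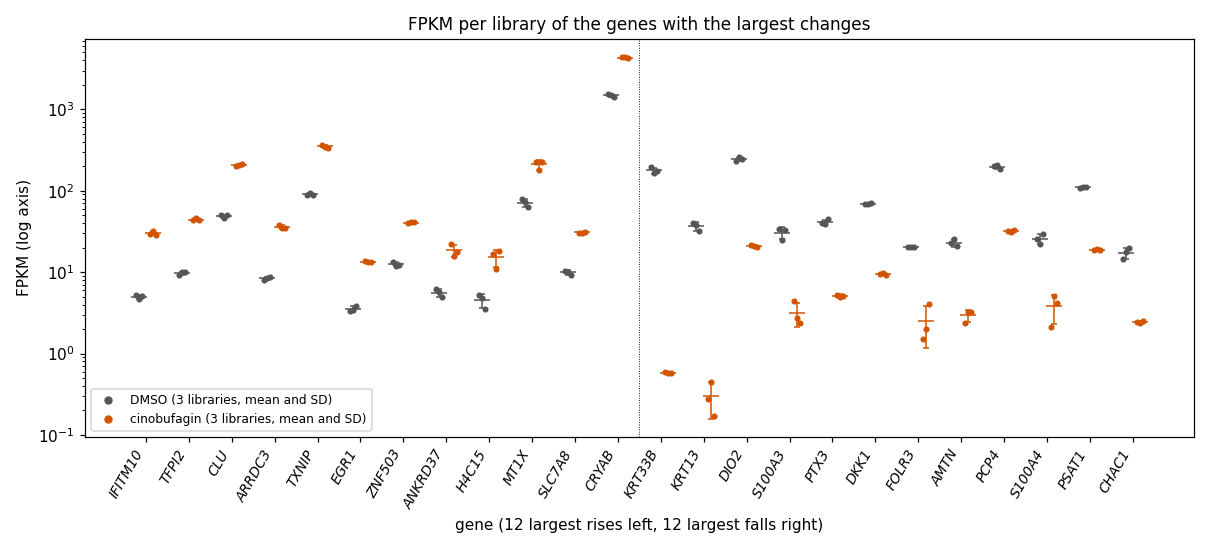
FPKM on a log axis for the 12 largest rises (left of the dotted line) and the 12 largest falls (right), in 3 DMSO libraries (grey points) and 3 cinobufagin libraries (orange points), with the mean (horizontal dash) and SD (bars). The groups do not overlap for any of these genes, and KRT33B has the widest gap, from a mean of 178 FPKM to 0.577.

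The largest rise by the same rule was that of IFITM10 (gene ID 402778, chromosome 11, 1732410 to 1750591), a member of the interferon-induced transmembrane family. Its level was 6.03-fold higher, at 4.98 ± 0.307 FPKM in DMSO and 30.1 ± 1.75 in cinobufagin libraries (SD, n = 3 each; log2 fold change 2.38, SE 0.06, limma adjusted p = 1.23e-10). TFPI2, a secreted serine protease inhibitor gene, went from 9.71 ± 0.438 to 44.3 ± 1.49 FPKM (log2 fold change 2.08, SE 0.05, limma adjusted p = 7.41e-11). CLU (gene ID 1191, chromosome 8, 27596917 to 27615031), which encodes the secreted chaperone clusterin, was 4.27-fold higher, at 48.6 ± 2.23 and 208 ± 5.35 FPKM (log2 fold change 2.07, SE 0.04, limma adjusted p = 2.48e-11). The arrestin-fold genes ARRDC3 and TXNIP, the latter an inhibitor of thioredoxin and of glucose uptake, rose by 1.98 and 1.94 on the log2 scale. TXNIP (gene ID 10628, chromosome 1, 145992435 to 145996600) reached 350 ± 12.7 FPKM from 90.4 ± 3.38. The immediate-early transcription factor gene EGR1 rose by 1.68, the zinc finger gene ZNF503 by 1.62 and the hypoxia-induced gene ANKRD37 by 1.56. The metallothionein gene MT1X, the amino acid transporter gene SLC7A8 and the histone gene H4C15 each rose by 1.54 on the log2 scale. CRYAB, the small heat shock protein alpha B-crystallin, went from 1494 ± 65.3 to 4334 ± 73.9 FPKM (log2 fold change 1.54, SE 0.05, limma adjusted p = 3.11e-10). H4C15 encodes the same protein as H4C14 from a near-identical copy, and CRYAB overlaps HSPB2 on the opposite strand, so reads of both pairs are uncertain.

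Of 33 gene lists fixed in advance, 27 had at least 5 tested genes and 16 shifted against the other genes, 4 upward and 12 downward (camera, preset correlation of 0.01, adjusted p under 0.05). With an estimated correlation 4 lists were called: DNA replication, the ATF4 and integrated stress response, nucleolar ribosome assembly and inflammatory cytokines. For each of the 16 lists, the adjusted p with an estimated correlation was the highest of any alternative run with camera. Member counts adjusted over the list alone equalled those over all genes tested, except in the 6 lists where both are given.

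**Figure D2:**
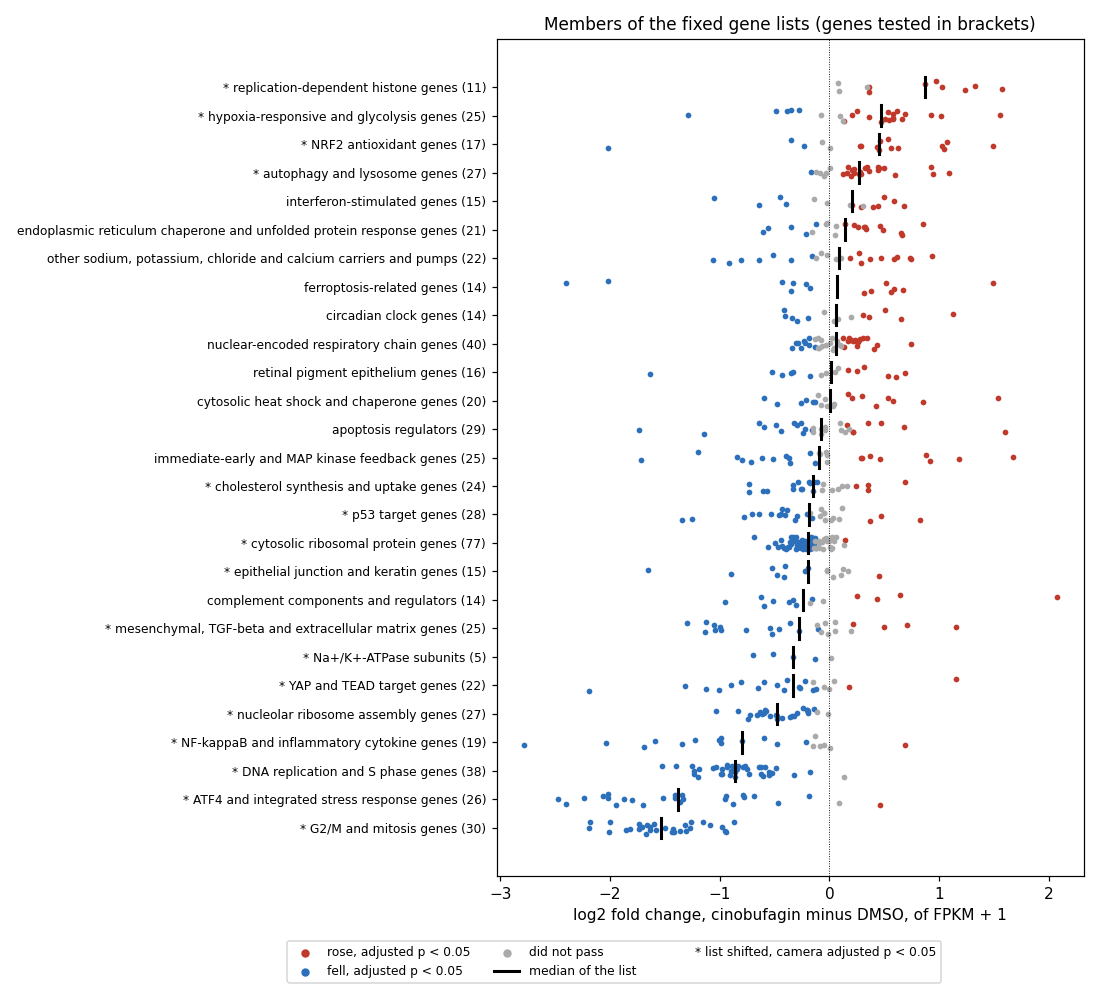
Log2 fold change of FPKM + 1, cinobufagin minus DMSO (horizontal axis), for each tested member of the 27 gene lists tested, with genes that rose in red, genes that fell in blue, genes that did not pass in grey and the median of each list as a black bar. The 30 mitosis genes lie lowest, with a median of -1.54, and the 11 genes of the histone list lie highest, with a median of 0.87.

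Transcripts of the sodium pump itself were modestly lower. The regulatory subunit gene FXYD5 went from 34.7 ± 1.70 to 21.1 ± 2.05 FPKM (SD, n = 3 each), a log2 fold change of -0.69 (SE 0.07, limma adjusted p = 2.88e-06). ATP1B3 fell by 0.13 (SE 0.04, limma adjusted p = 0.0128). It missed the threshold at about the same size without DMSO replicate 3 (log2 fold change -0.119, limma adjusted p = 0.0532) and without cinobufagin replicate 2 (-0.117, 0.0579), in a range of 0.00325 to 0.0579 over its alternatives. The main beta subunit gene ATP1B1 was at 126 ± 3.48 and 127 ± 5.22 FPKM and did not pass (limma adjusted p = 0.744). In all, 0 of the 5 subunit genes tested rose, 4 fell and 1 did not pass (median log2 fold change -0.33, camera adjusted p = 0.0448). The list's camera adjusted p was 0.206 with an estimated correlation, 0.0525 without the mean-variance trend, 0.0774 after quantile normalization, 0.0541 without DMSO replicate 1 and 0.069 without cinobufagin replicate 2, with 0.0372 as the lowest of any alternative run with camera.

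Other sodium, potassium, chloride and calcium carriers moved both ways. Of 22 tested, 10 rose (11 adjusted over the list alone), 7 fell (7) and 5 did not pass (median log2 fold change 0.08, camera adjusted p = 0.905). The inositol trisphosphate receptor genes parted, with ITPR3 falling from 45.5 ± 1.57 to 21.2 ± 0.402 FPKM and ITPR1 rising from 2.43 ± 0.123 to 5.54 ± 0.0862. The sodium bicarbonate cotransporter gene SLC4A7 fell by 0.91 and the potassium channel gene KCNQ5 fell by 0.80 on the log2 scale.

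The fixed lists of mitosis and of DNA replication fell almost throughout. All 30 mitosis genes tested fell, 26 of them by at least 1 on the log2 scale (median log2 fold change -1.54, camera adjusted p = 3.04e-19; adjusted p = 0.0683 with an estimated correlation). KIF20A, a kinesin of cytokinesis, was 5.70-fold lower, at 18.2 ± 0.633 and 3.19 ± 0.275 FPKM (log2 fold change -2.20, SE 0.07, limma adjusted p = 3.21e-10). CDC20, an activator of the anaphase-promoting complex, fell by 2.19, its ubiquitin-conjugating partner UBE2C fell by 2.01 and the kinase gene PLK1 fell by 2.00 on the log2 scale. Among 38 DNA replication and S phase genes, 0 rose, 37 fell and 1 did not pass (median log2 fold change -0.86, camera adjusted p = 6.4e-17; adjusted p = 0.0105 with an estimated correlation). UHRF1, which maintains DNA methylation at replication forks, went from 13.3 ± 0.198 to 3.94 ± 0.125 FPKM, a log2 fold change of -1.53 (SE 0.06, limma adjusted p = 1.72e-09). Thymidine kinase TK1 was 2.72-fold lower, and the origin licensing and firing genes CDC45 and CDT1 fell by 1.25 and fell by 1.24 on the log2 scale. The exception was cyclin E1, CCNE1, at 5.57 and 6.21 FPKM (limma adjusted p = 0.131).

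Most genes of the histone list went the other way. In the histone list, 10 of whose 11 tested genes are replication-dependent, 8 genes rose (9 adjusted over the list alone), 0 fell and 3 did not pass. The median log2 fold change was 0.87 (camera adjusted p = 0.00407; adjusted p = 0.114 with an estimated correlation). The linker histone gene H1-2 went from 22.7 ± 1.70 to 47.3 ± 2.70 FPKM (log2 fold change 1.03, SE 0.06, limma adjusted p = 5.14e-08). H2AC6 rose by 1.24, H2BC4 by 1.33 and H4C14 by 1.58 on the log2 scale. H2BC4 was low, at 0.303 ± 0.210 FPKM in DMSO and 2.26 ± 0.320 in cinobufagin libraries. It passed the filter only through the cinobufagin libraries. With no filter on low values the median was 0.30 and the list was not called (camera adjusted p = 0.112), in a range of 0.00119 to 0.114 over its alternatives run with camera. These genes share sequence with other copies, and how reads were divided among the copies is not given in the sources used here.

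Genes of the ATF4 and integrated stress response, which amino acid shortage and other stresses induce, fell strongly. Of 26 tested, 1 rose, 24 fell and 1 did not pass, and 16 fell by at least 1 on the log2 scale (median log2 fold change -1.38, camera adjusted p = 1.81e-15; adjusted p = 0.0105 with an estimated correlation). PSAT1 (gene ID 29968, chromosome 9, 78297143 to 78330093), an enzyme of serine synthesis, was 5.81-fold lower, at 110 ± 2.35 and 18.96 ± 0.211 FPKM (SD, n = 3 each; log2 fold change -2.48, SE 0.04, limma adjusted p = 2.44e-12). CHAC1, which degrades glutathione, went from 17.3 ± 2.59 to 2.44 ± 0.0874 FPKM (log2 fold change -2.40, SE 0.09, limma adjusted p = 1.72e-09). The pseudokinase gene TRIB3 fell by 2.23 and CTH, which makes cysteine from cystathionine, fell by 2.07 on the log2 scale. The lipoprotein receptor gene VLDLR was the member that rose, by 0.46 on the log2 scale, and was named after its value was seen.

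Endoplasmic reticulum chaperone and unfolded protein response genes were not called as shifted against the other genes. The list is among 7 that fry called and camera did not (direction up, fry adjusted p = 0.000983). Of 21 tested, 11 rose, 5 fell and 5 did not pass (median log2 fold change 0.14, camera adjusted p = 0.403). The co-chaperone genes DNAJB9 and DNAJC3 rose by 0.85 and 0.65 and the degradation adaptor SEL1L by 0.66 on the log2 scale, while the disulfide isomerase PDIA6 fell by 0.61. Among 20 heat shock and chaperone genes, a list fixed as cytosolic that also holds the mitochondrial HSPD1 and HSPE1, 8 rose, 6 fell and 6 did not pass (median log2 fold change 0.01, camera adjusted p = 0.833). HSPA1A and HSPA1B, nearly identical genes of inducible HSP70 whose reads are hard to separate, rose by 0.58 and 0.85, while the chaperonin HSPD1 fell by 0.60 on the log2 scale.

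Genes for making ribosomes fell. Of 27 nucleolar ribosome assembly genes, 0 rose, 25 fell and 2 did not pass (median log2 fold change -0.48, camera adjusted p = 2.3e-08; adjusted p = 0.0246 with an estimated correlation). BOP1, a factor of large subunit maturation, was 2.14-fold lower, at 27.8 ± 5.06 and 12.98 ± 1.33 FPKM (log2 fold change -1.03, SE 0.11, limma adjusted p = 4.83e-06). The RNA helicase DDX21 fell by 0.83, WDR43 fell by 0.74 and the methyltransferase fibrillarin, FBL, fell by 0.72 on the log2 scale. Of 77 ribosomal protein genes, 1 rose (2 adjusted over the list alone), 56 fell (57) and 20 did not pass. Their shift was small, with a median log2 fold change of -0.19 (camera adjusted p = 8.79e-09; adjusted p = 0.469 with an estimated correlation). RPL3 went from 2772 ± 136 to 1719 ± 20.5 FPKM, RPSA fell by 0.56, RPS3 fell by 0.50 and RPS24 fell by 0.47 on the log2 scale. Ribosomal protein genes have many pseudogene copies, which makes their read assignment uncertain.

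Inflammatory cytokine genes were lower. Among 19 NF-kappaB and inflammatory genes, 1 rose, 13 fell and 5 did not pass (median log2 fold change -0.79, camera adjusted p = 8.07e-06; adjusted p = 0.0443 with an estimated correlation). The neutrophil chemokine CXCL8 was 4.22-fold lower, at 114 ± 4.68 and 27.0 ± 1.59 FPKM (SD, n = 3 each; log2 fold change -2.04, SE 0.05, limma adjusted p = 7.93e-11). CXCL3 fell by 1.70 and IL1B fell by 1.59 on the log2 scale. The pathway genes NFKB1, at 10.1 and 9.44 FPKM, and NFKBIA, at 23.5 and 23.6 FPKM, did not pass (limma adjusted p = 0.214 and 0.907). The member that rose was the chemokine CCL20, by 0.69 on the log2 scale, named after its value was seen. Interferon-stimulated genes were mixed, with 7 of 15 higher (9 adjusted over the list alone), 4 lower (4) and 4 that did not pass (median log2 fold change 0.21, camera adjusted p = 0.8). IRF7 rose by 0.68 and IFIT2 by 0.59, while OAS3 fell by 1.05 and IFI27 fell by 0.64 on the log2 scale. Of 14 complement genes, 4 rose, 8 fell and 2 did not pass (median log2 fold change -0.24, camera adjusted p = 0.237). Beside CLU, the regulator CFI rose by 0.64, whereas the protease C1R fell by 0.96 and the inhibitor SERPING1 fell by 0.62 on the log2 scale.

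Matrix, adhesion and mechanical response genes were lower on balance. Of 22 YAP and TEAD target genes, 2 rose, 16 fell and 4 did not pass (median log2 fold change -0.33, camera adjusted p = 3.99e-05; adjusted p = 0.0683 with an estimated correlation). F3 (gene ID 2152, chromosome 1, 94529225 to 94541800), the coagulation starter tissue factor, was 4.61-fold lower, at 322 ± 7.96 and 69.9 ± 0.321 FPKM (log2 fold change -2.19, SE 0.04, limma adjusted p = 3.06e-12). The kinase gene NUAK2 fell by 1.32 on the log2 scale. CCN2, a matricellular protein gene, rose instead, from 58.0 ± 2.11 to 130 ± 3.79 FPKM (log2 fold change 1.15, SE 0.04, limma adjusted p = 1.35e-09). Of 25 mesenchymal, TGF-beta and matrix genes, 4 rose, 14 fell and 7 did not pass (median log2 fold change -0.28, camera adjusted p = 0.00208; adjusted p = 0.311 with an estimated correlation). The fibronectin receptor subunit ITGA5 and the growth factor TGFB2 each fell by 1.13 on the log2 scale. Of 15 epithelial junction and keratin genes, 1 rose, 8 fell and 6 did not pass (median log2 fold change -0.19, camera adjusted p = 0.0481; adjusted p = 0.369 with an estimated correlation). KRT7 fell by 1.65, the tight junction gene CLDN1 fell by 0.89, KRT8 fell by 0.52 and KRT18 fell by 0.48 on the log2 scale. The epithelial list was also not called without the mean-variance trend (camera adjusted p = 0.0573), with no filter (0.0726, median -0.0224), without DMSO replicate 1 (0.0544) or without cinobufagin replicate 2 (0.0744), and 0.0306 was the lowest of any alternative run with camera.

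Autophagy and lysosome genes rose together by small amounts. Of 27 tested, 21 rose, 1 fell and 5 did not pass (median log2 fold change 0.27, camera adjusted p = 0.0014; adjusted p = 0.0683 with an estimated correlation). The autophagosome gene GABARAPL1 was 2.17-fold higher, at 24.7 ± 1.67 and 53.6 ± 1.38 FPKM (SD, n = 3 each; log2 fold change 1.09, SE 0.05, limma adjusted p = 1.15e-08). The autophagy-starting kinase gene ULK1 rose by 0.94, WIPI1 by 0.92 and the lysosomal sialidase gene NEU1 by 0.60 on the log2 scale. MAP1LC3B, at 98.9 and 95.2 FPKM, and TFEB, at 3.72 and 3.31 FPKM, did not pass (limma adjusted p = 0.292 and 0.36).

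Antioxidant genes regulated by NRF2 were higher, with 12 of 17 risen, 3 fallen and 2 that did not pass (median log2 fold change 0.45, camera adjusted p = 0.0131; adjusted p = 0.114 with an estimated correlation). The ferritin light chain gene FTL was 2.81-fold higher, at 2155 ± 169 and 6058 ± 47.8 FPKM (log2 fold change 1.49, SE 0.06, limma adjusted p = 1.62e-09). GCLC, an enzyme of glutathione synthesis, rose by 1.07 and the quinone reductase NQO1 by 1.04 on the log2 scale. SLC7A11, the cystine importer that also belongs to the stress response list, fell by 2.01. Of 14 ferroptosis-related genes, which include CHAC1, SLC7A11 and FTL, 7 rose, 7 fell and 0 did not pass (median log2 fold change 0.07, mean -0.10, camera adjusted p = 0.905). The polyamine enzyme SAT1 rose by 0.67 on the log2 scale.

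Hypoxia-responsive and glycolysis genes were mostly higher. Of 25 tested, 17 rose (18 adjusted over the list alone), 5 fell (5) and 3 did not pass (median log2 fold change 0.47, camera adjusted p = 0.0131; adjusted p = 0.369 with an estimated correlation). The glycolytic genes ALDOA and GAPDH rose by 1.02 and 0.92 on the log2 scale, and GAPDH went from 5178 ± 240 to 9806 ± 72.3 FPKM. The carbonic anhydrase gene CA9, a marker of hypoxia, fell from 190 ± 13.5 to 76.8 ± 3.23 FPKM (log2 fold change -1.29, SE 0.05, limma adjusted p = 3.23e-09). Nuclear-encoded respiratory chain genes changed little, with 17 of 40 higher, 9 lower and 14 that did not pass (median log2 fold change 0.06, camera adjusted p = 0.842). NDUFA2 rose by 0.74, SDHC by 0.43, NDUFC1 by 0.41 and UQCRQ by 0.35 on the log2 scale. Mitochondrially encoded genes were not analysed here. Of 24 cholesterol synthesis and uptake genes, 4 rose, 14 fell and 6 did not pass (median log2 fold change -0.15, camera adjusted p = 0.0448; adjusted p = 0.369 with an estimated correlation). FDPS and EBP each fell by 0.73, while TM7SF2 rose by 0.69 on the log2 scale. The cholesterol list was not called without the mean-variance trend (camera adjusted p = 0.0531), without DMSO replicate 1 (0.0541) or without cinobufagin replicate 2 (0.0629) or 3 (0.0641), and 0.0285 was the lowest of any alternative run with camera.

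Targets of the tumour suppressor p53 were lower on balance. Of 28 tested, 3 rose, 15 fell and 10 did not pass (median log2 fold change -0.19, camera adjusted p = 0.00228; adjusted p = 0.0683 with an estimated correlation). The DNA damage sensor DDB2 was 2.62-fold lower, at 14.8 ± 0.372 and 5.64 ± 0.791 FPKM (log2 fold change -1.26, SE 0.08, limma adjusted p = 9.04e-08). The stress cytokine GDF15 went from 1.80 ± 0.263 to 0.103 ± 0.0379 FPKM, and SESN2, which also belongs to the stress response list, fell by 0.78 on the log2 scale. TP53INP1 rose by 0.83. MDM2, the ubiquitin ligase of p53, was at 22.6 and 21.7 FPKM and did not pass (limma adjusted p = 0.489). Of 29 apoptosis regulators, 7 rose, 12 fell and 10 did not pass (median log2 fold change -0.08, camera adjusted p = 0.151). The pro-apoptotic gene BMF rose from 2.33 ± 0.121 to 9.12 ± 0.237 FPKM and CASP9 rose by 0.68 on the log2 scale. BIRC5, a mitotic survival factor that also belongs to the mitosis list, fell by 1.73, and the pro-apoptotic gene HRK fell by 1.15. Immediate-early and MAP kinase feedback genes were divided, with 8 of 25 higher, 12 lower and 5 that did not pass (median log2 fold change -0.10, camera adjusted p = 0.135). EGR1 and the ERK phosphatase gene DUSP6 rose, DUSP6 by 1.18, while FOSL1 fell by 1.72 and MYC fell by 1.20 on the log2 scale. Of 14 circadian clock genes, 5 rose (6 adjusted over the list alone), 5 fell (5) and 4 did not pass (median log2 fold change 0.06, camera adjusted p = 0.834). CRY2 rose by 1.13, TEF by 0.65 and DBP by 0.51, while NR1D1 fell by 0.41 on the log2 scale.

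Genes of the retinal pigment epithelium itself were divided, with 6 of 16 higher, 6 lower and 4 that did not pass (median log2 fold change 0.01, mean -0.05, camera direction down, adjusted p = 0.842). The visual cycle gene RDH10 was 3.28-fold lower, at 40.0 ± 2.26 and 12.2 ± 0.802 FPKM (SD, n = 3 each; log2 fold change -1.63, SE 0.06, limma adjusted p = 1.22e-09). The phagocytosis receptor MERTK rose by 0.69, the transcription factor OTX2 by 0.61 and the retinol dehydrogenase RDH5 by 0.54 on the log2 scale. Marker lists of other cell types held too few tested genes for a list test. Of 14 neuron and photoreceptor markers 3 were tested, and TUBB3 rose by 0.78 and MAP2 by 0.36 on the log2 scale, while SYT1 was at 8.08 and 8.21 FPKM (limma adjusted p = 0.782). The endothelial marker EGFL7 fell by 0.28 on the log2 scale (limma adjusted p = 0.00838). It missed the threshold once the trend with length and GC content was removed (log2 fold change -0.131, limma adjusted p = 0.165), in a range of 0.00174 to 0.165 over its alternatives. The macrophage marker CD68, which is lysosomal, fell by 0.56, and the leukocyte gene PTPRC was listed at 0 in every library. The fibroblast marker FAP fell by 1.14, while PDGFRB was at 13.7 and 13.9 FPKM (limma adjusted p = 0.844). The melanocyte markers SLC45A2, GPR143 and PMEL, genes that pigmented epithelium also uses, fell by 0.76, fell by 0.55 and fell by 0.35 on the log2 scale, and TYRP1 did not pass (limma adjusted p = 0.669).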

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

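The removal of the length and GC trend was chosen after seeing the data, and all other alternatives before. Read totals are not given in the sources used here, so the counting error of genes near 1 FPKM could not be computed. Counts of genes changed ranged from 6457 to 8211 over other settings without a fold minimum, and from 7131 to 7591 when 1 library was left out, against 7849. The number of lists called by camera at the preset correlation ranged from 13 to 16, and the share of risen genes from 52.1% (median centring) to 59.7%, against 58.0%. Of 128 named genes past the threshold, 126 kept their call in every alternative that tested them, the fold minimum apart, the exceptions being ATP1B3 and EGFL7. The filter of at least 5 FPKM tested 120 of the 129 named genes and not the sodium pump list, and the fits without 1 library tested 126 or 128. Of 16 lists, 12 kept theirs in every alternative that tested them, the estimated correlation apart, and the other lists were the sodium pump, histone, cholesterol and epithelial lists. A minimum log2 fold change of 1 left 498 genes, 111 higher and 387 lower, by its construction, and an estimated correlation left 4 lists, where the cause was not tested. Directions turned only in results that were not called, and the cause was not tested. These were the ion carriers with the length and GC trend removed (median 0.0668, camera direction down), the retinal pigment epithelium list after quantile normalization (median 0.0488, direction up), the interferon list with no filter (median -0.0869) and ATP1B1 after median centring (-0.0254). With 1 library left out, the camera direction turned to down for the ferroptosis list (median 0.0449 to 0.0933 over the 6 fits) and the respiratory chain list (0.0341 to 0.0882), and ATP1B1 ranged from -0.0111 to 0.0476. Medians of other lists that were not called moved by over 1.5 times or turned when a library was left out. Without DMSO replicate 1 the complement median was -0.136 and the apoptosis median -0.128, and without cinobufagin replicate 1 the interferon median was 0.140. Over the 6 such fits the circadian median ranged from 0.0253 to 0.105, the heat shock median from -0.0106 to 0.0119 and the retinal pigment epithelium median from -0.0226 to 0.0303. With the replicate number as a block, 7690 genes changed, 4454 higher and 3236 lower, and 15 lists were called. The cholesterol list was the one lost (camera adjusted p = 0.0506, in a range of 0.0285 to 0.369 over its alternatives run with camera). Deviations from the group means correlated at -0.05, -0.10 and -0.01 between libraries of the same number, so the numbers were not taken to pair the samples. The fry test called 23 lists, 7 of them not called by camera. These 7 were the ion carrier, immediate-early, endoplasmic reticulum chaperone, heat shock, apoptosis, ferroptosis and circadian lists.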

Other observations

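The genes in the first 2 paragraphs of this part, the scan of gene families, and the tests of scaling, of length and GC content, of unequal RNA capture, of neighbouring genes and of paralogs were chosen after results were seen. The tests on synthetase genes, short transcripts and replacement histone genes also address patterns first seen in the results. Keratin genes fell as a family. A scan of 201 symbol families with at least 8 tested genes called 3 with camera, keratins (KRT), large ribosomal subunit proteins (RPL) and the MCM stem, and 0 with an estimated correlation. All 3 were also called after quantile normalization, after median centring and without each library in turn. Of 11 keratin genes 10 fell and 1 rose, counts that quantile normalization and median centring also gave (median log2 fold change -1.56, camera adjusted p = 2.75e-05; adjusted p = 0.746 with an estimated correlation). Without any 1 of the DMSO libraries 8 keratin genes were tested, and the median was -0.994 without replicate 1 and -1.01 without replicate 3. KRT33B, KRT13 and KRT31 lay below 1 FPKM with cinobufagin, so they passed the filter only when all DMSO libraries were kept. Of 50 RPL genes 3 rose and 35 fell (median -0.206), and after quantile normalization 6 rose and 29 fell (median -0.123). Beside KRT33B, the hair keratin gene KRT34 fell by 2.20 and KRT31 fell by 1.56 on the log2 scale, and the keratin-associated gene KRTAP2-3 went from 11.6 ± 0.817 to 0.680 ± 0.263 FPKM (SD, n = 3 each). The interleukin 7 receptor gene IL7R went from 10.1 ± 0.318 to 0.290 ± 0.0173 FPKM, a log2 fold change of -3.10 (SE 0.07, limma adjusted p = 3.8e-11).

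Both arrestin-fold genes known to respond to glucose were higher, since ARRDC4 rose by 1.12 on the log2 scale beside TXNIP, while ARRDC2 fell by 0.20. Beside the metallothionein gene MT1X, MT2A rose by 0.71, MT1E by 0.39 and MT1F by 0.35 on the log2 scale, while MT1M was too low to be tested and the genes were not tested as a group. CRYAB and its divergent neighbour HSPB2 moved apart, HSPB2 from 13.4 ± 1.06 to 2.48 ± 0.520 FPKM (log2 fold change -2.06, SE 0.10, limma adjusted p = 1.29e-08). The 2 genes overlap on opposite strands and the strand setting is not given, so the HSPB2 values are uncertain. ATF4 itself went from 320 ± 1.81 to 165 ± 4.36 FPKM (log2 fold change -0.95, SE 0.04, limma adjusted p = 2.11e-09). The cell cycle inhibitor CDKN1A fell by 0.46 on the log2 scale while replication and mitosis genes fell.

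The count of genes changed was compared with other splits of the 6 libraries into 3 and 3. The real split gave 7849 genes and the highest of the other splits 1 gene, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Every other split mixes cinobufagin and DMSO libraries in both groups. The treatment difference then adds to the spread within groups, so low counts there follow from the construction.

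A hypothesis for the fall of the stress response list is lower transcription driven by ATF4. It was tested on cytosolic aminoacyl-tRNA synthetase genes outside the list, of which those linked to ATF4 had a median log2 fold change of -0.87 (10 of 10 fell) and the others -0.03 (3 of 8 fell and 2 rose). The difference of -0.84 had an exact two-sided permutation p = 0.0016 over 43758 assignments, across genes, which are not independent replicates. After median centring the list's median was -1.42. The library medians of the tested genes already lay between 3.66 and 3.72 on the log2 scale. Centring could therefore move the list little and cannot decide on the authors' scaling. A length or GC trend is argued against, with a list median of -1.39 after its removal. These values are consistent with lower ATF4 activity, which stays a hypothesis, and ATF4 protein was not measured.

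Replication-dependent histone genes rose while DNA replication genes fell, and 3 explanations were tested on the 10 replication-dependent genes of the list (8 rose, 0 fell, median log2 fold change 0.92). A bias toward short transcripts is argued against by 107 other genes under 800 nt, with a median of -0.0419. Lengths within the histone list do not argue against it. Of the 10 histone genes, 5 have a longest transcript of 1547 to 2250 nt. Among them H4C14 rose by 1.58, H2AC6 by 1.24 and H2BC21 by 0.36, while H4C8 and H2AC11 did not pass. The other 5, under 800 nt, all rose, by 0.36 to 1.33 on the log2 scale. A higher output of all histone genes is argued against by 9 polyadenylated replacement histone genes, with a median of -0.11. Unequal capture of RNA without a poly(A) tail stays open. The histone genes' median deviation from the group mean spanned 0.15 over the cinobufagin libraries, against a median of 0.05 in 10000 expression-matched random sets (one-sided permutation p = 0.0025). In the DMSO libraries it was 0.040, 0.004 and -0.050. The sets were matched on level, not on length or sequence shared between copies, so the comparison cannot decide on capture. A range within a group sets no limit on a capture difference between the groups, so capture may account for all, part or none of the rise. A biological candidate, more polyadenylated histone transcripts in cells that divide less, was not tested.

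Several of the largest falls lie close together, such as KRT33B with KRT13 and S100A2, S100A3 and S100A4. Among the 100 largest falls of 5793 genes at or above the median level, which leaves out KRT34 and KRTAP2-3, 10 pairs lay within 500 kb, but 4 of them are these same pairs, so that count decides nothing. Pairs from different symbol families numbered 6, against a median of 5 in 2000 random sets drawn from those genes (one-sided permutation p = 0.36), which leaves open whether neighbours fell together. Reads moved to the paralog KRT33A are argued against, since the sum of KRT33A and KRT33B fell by 6.81 on the log2 scale, from 178 to 0.593 FPKM. A shared regulatory region was not tested.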
